A study of Homo sapiens with 11 samples.

How the data were processed

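Newly made RNA was measured in 2 human pancreatic cancer cell lines. In Bru-seq, cells take up bromouridine for 0.5 h, the labelled RNA is pulled down with an antibody at once (0 h chase) and sequenced, so that the reads come from nascent RNA. In BruChase-seq, the label is followed by 6 h without it, so that the reads come from RNA of that age. BxPC-3 gave 3 nascent libraries: 2 CRISPR clones with KMT2D knocked out (KO1 and KO2) and 1 control line without a guide RNA. PANC-1 gave 8 libraries: vehicle and TGF-β for 1, 24 and 72 h, each as 1 nascent and 1 chased library. The labels do not say whether TGF-β stayed on the cells during the chase. Per the labels' protocols, a step with actinomycin D that makes reads strand-specific applies to certain samples, and which ones is not given in the sources used here. Genes that overlap each other, or that share reads with near-identical copies, are therefore reported as uncertain.

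Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.3.3, STAR 2.5.3a and bedtools 2.16.2 were used with the human genome build GRCh38 (hg38). Their order and settings and the gene annotation are not given in the sources used here. For each library the authors deposited 57733 genes with versioned Ensembl identifiers, symbols and coordinates. The first unit used was expected counts, which the authors deposited per gene as amounts that need not be whole (44.2% to 58.5% of the values above 0 lay within 0.01 of a whole number). For 86.4% of the genes the deposited length equals the whole span of the gene, so introns are included. The second unit is RPKM, which the authors deposited beside the counts, and these values were used only to check that they are the counts per kilobase, scaled to 1 fixed total for each library. The sum of the expected counts was 23302381 to 55001983 per library. Because the counts come from PCR-amplified reads, all counting intervals and floors given here cover counting error only. Coordinates are given 1-based on GRCh38, and gene symbols are those of the deposited files, some of them older names.

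Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F-test, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The knockout comparison used the 3 BxPC-3 libraries and has 1 residual degree of freedom, which comes from the difference between the clones alone. The moderated test gave it an infinite prior weight, so the spread of each gene was taken from the trend over all genes. The TGF-β comparison used the 8 PANC-1 libraries in a single additive model of assay and condition, with 3 residual degrees of freedom. It estimates an effect common to nascent and chased RNA, and counts any effect that differs between them as spread. The same model gave the comparison of chased with nascent RNA. Because nothing in the labels says that libraries came from separate cultures, p-values measure only the spread between these samples, which may in part be technical. All fold changes are log2 values given with their standard error (SE).

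Ratios of 2 PANC-1 libraries were computed as log2 of TMM-scaled counts with a pseudocount of 0.5, over genes with a mean of at least 20 counts in the libraries of that assay. They have no replicate check and no p-value. Their 95% counting intervals are exact conditional binomial intervals. A gene was listed when the ratio was at least 2-fold. The change of the chase to nascent ratio is the log2 ratio of chased to nascent RNA under TGF-β minus that under vehicle. A fold against a library or group with 0 counts is a lower bound, computed against a floor of 3 counts per library. With 1 to 3 counts, the ratio is given with its counting interval.

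Before the data were examined, 30 gene lists were fixed. They cover TGF-β and BMP targets, mesenchymal, epithelial and matrix genes, the activin pathway, p38, JNK and AP-1 signalling, immediate early genes, histone H3 lysine 4 (H3K4) methyltransferase complexes and the pancreatic cancer subtypes. The H3K4 methyltransferase list also holds other chromatin enzyme genes, namely EP300, CREBBP, KDM1A, KDM5A, KDM5B, KDM5C and EZH2, some of which encode enzymes that remove the mark. Further lists cover the cell cycle, growth arrest, histones, metabolism, hypoxia, interferon, inflammation, stress responses, p53 targets, ribosomal proteins, zinc finger factors and markers of other cell types. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the members of a list move one way on balance. With an estimated correlation, camera tests against the residual degrees of freedom of the fit, 1 for the knockout and 3 for PANC-1. A call lost in that setting can reflect these few degrees of freedom and need not reflect correlation among genes. Adjustment was over the lists of a comparison. For ratios of 2 libraries, the median of a list was set against 10000 random lists of the same size matched on mean expression. The rule for naming genes was also fixed then: a fixed set with KMT2D, INHBA, FST, SMAD7, CDH1, VIM and SLC2A3 in each comparison, the 12 most higher and 12 most lower knockout genes past the threshold that moved the same way in both clones, the 8 and 8 with the largest nascent ratio at each time of TGF-β with the same sign in chased RNA, the 10 and 10 of chased against nascent RNA, the 4 and 4 of the change of the chase to nascent ratio at 24 and 72 h, and up to 4 members of each list, passing members first. Clone-based, antisense and intergenic names were left out. A few genes that the rule picks are not used here.

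The alternatives tried were median-of-ratios scaling, library totals alone, no expression filter, a minimum mean of 100 counts, a pseudocount of 5, DESeq2 1.42.0, limma-voom, all 11 libraries in a single fit, and each library left out in turn. The methods were tested on simulated data with known changes, drawn from the real means and library sizes in 3 simulations. In simulated knockout data of 21040.7 genes on average, 2.0% of 2-fold, 19.7% of 4-fold and 52.0% of 8-fold changes were recovered, with 1.33 unchanged genes called. In simulated TGF-β data for 72 h (19683.7 genes), the shares were 52.0%, 83.3% and 94.0%, with 8 unchanged genes called. In simulated chase data (19646.3 genes), they were 66.7%, 95% and 96.7%, with 7.33 unchanged genes called. For ratios of 2 libraries, 198 of 200 genes changed 4-fold passed 2-fold in simulated data, as did 28 unchanged genes of 16843. These ratios were simulated with counting error alone and no spread between libraries. The 28 is therefore not an error rate for the real lists of genes past 2-fold. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. No genome sequence was used here, so GC content was not examined.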

Results

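The data set holds nascent RNA of BxPC-3 cells with and without a KMT2D knockout, and nascent and chased RNA of PANC-1 cells treated with TGF-β. BxPC-3 and PANC-1 are established human pancreatic cancer lines, and BxPC-3 is known to lack SMAD4, the common mediator of SMAD signalling. TGF-β is a cytokine that signals through SMAD proteins and can drive epithelial cells toward a mesenchymal state. The title of the series names a link from KMT2D through TGF-β to a non-canonical activin pathway and cell plasticity. The summed counts were 49704350 for clone KO1, 40589889 for clone KO2 and 28953048 for the BxPC-3 control line. In PANC-1 nascent RNA they were 55001983 with vehicle, 44554693 after 1 h of TGF-β, 52634992 after 24 h and 40314792 after 72 h. In PANC-1 RNA after 6 h of chase they were 39658700, 39246853, 36355793 and 23302381 in the same order. Every PANC-1 group and the BxPC-3 control group holds 1 library, and the knockout group holds 2.

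KMT2D, which encodes a histone H3 lysine 4 methyltransferase that acts mainly at enhancers, is the targeted gene and was examined first. KMT2D lies on chromosome 12 from 49019198 to 49055324 on the minus strand (ENSG00000167548.14). Its nascent level in BxPC-3 was 46.6 CPM, a count scaled to library size, in the control line (1398 counts), 27.4 in KO1 (1238 counts) and 25.8 in KO2 (1110 counts). The fitted log2 fold change was -0.81 ± 0.47 (SE, 2 clones against 1 control line) with an adjusted p of 0.561 in edgeR, so the lower level in both clones did not pass the test. The window of 50 neighbouring genes that holds KMT2D (48688458 to 52814551) had median log2 ratios of -0.76 in KO1 and -0.53 in KO2, so its neighbourhood was lower as well. All such windows on chromosome 12 from 14522 to 62622213 were lower in both clones. The lower KMT2D level therefore cannot be set apart from that of the region. Counts summed over a whole gene do not show whether the edited sequence is intact. In PANC-1, KMT2D was at 28.9, 26.9, 19.4 and 23.7 CPM in nascent RNA with vehicle and after 1, 24 and 72 h of TGF-β, and at 403, 321, 180 and 136 CPM in chased RNA.

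The first comparison asked which genes differ in nascent transcription between the KMT2D-knockout clones and the control line. Some mesenchymal and matrix genes rose in the clones and some epithelial genes fell, and camera calls for these lists were lost with an estimated correlation (adjusted p = 0.664). VIM, which encodes the mesenchymal filament protein vimentin, rose by 5.61 ± 0.94 (log2, 5 counts in the control, 559 and 181 in the clones), and VCAN, which encodes the matrix proteoglycan versican, rose by 8.85 ± 0.76 (7 counts; 7172 and 2568). INHBA, which encodes the activin A subunit, rose by 4.96 ± 0.87 (9 counts; 360 and 465), and FST, which encodes the activin-binding protein follistatin, rose by 2.13 ± 0.58. CDH1, which encodes the epithelial junction protein E-cadherin, fell by 1.58 ± 0.46. SMAD7, an inhibitor of TGF-β receptors, fell by 1.30 ± 0.43 with an adjusted p of 0.049 in edgeR, and 6 of the alternative settings did not call it. CDH1 was not called with median-of-ratios scaling (adjusted p = 0.056) or limma-voom (adjusted p = 0.091). SLC2A3, a glucose transporter, did not pass the expression filter in BxPC-3.

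In total, 486 genes rose and 720 fell among 21667 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and 1189 of these 1206 had the same direction in both clones. At least 2-fold in both clones, 1457 genes were higher and 1752 lower. Because the clones share a control library, unchanged clones drawn in 20 simulations also gave 1370.25 higher (1333 to 1419) and 908.95 lower (850 to 953) on average. Over genes, the log2 ratios of the 2 clones correlated with r = 0.670 against 0.525 in the simulations, with a covariance of 1.18 against 0.523. VCAN and VIM thus belong to a test whose spread rests on 2 clones. With all 11 libraries in a single fit, both clones gave 614 higher and 847 lower genes. With either clone left out of that fit, each BxPC-3 group holds a single library and the spread comes from PANC-1 alone. Gene counts of those fits are therefore not compared with these. A single control line cannot separate the loss of KMT2D from other differences between clones.

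Among 29 tested mesenchymal genes, 8 rose and 1 fell (14 and 2 when adjusted over the list alone). TAGLN, an actin-binding protein of contractile cells, rose by 4.47 ± 0.77, the cadherin CDH11 by 3.33 ± 0.73, fibronectin FN1 by 3.27 ± 0.83 and the collagen cross-linking enzyme LOX by 3.23 ± 0.77. ZEB1, a transcription factor that represses epithelial genes, rose by 2.47 ± 0.73, with log2 ratios of 3.29 in KO1 and 0.30 in KO2, and the receptor kinase AXL was the member that fell. The list was shifted upward by camera (adjusted p = 1.82e-07), with an adjusted p = 0.664 with an estimated correlation. Of 31 tested matrix genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 8.34e-06, and adjusted p = 0.664 with an estimated correlation). The basement membrane collagens COL4A1 and COL4A2 rose by 5.88 ± 0.73 and 3.65 ± 0.88, COL8A1 rose by 2.94 ± 0.60, and COL18A1 fell by 4.49 ± 0.79. Of 9 fibroblast markers, 3 rose and 1 fell (4 and 1 adjusted over the list alone), namely MFAP5 at 5.74 ± 0.74, FAP at 4.09 ± 0.85, PDPN at 3.62 ± 0.80 and FBLN1 at -1.72 ± 0.46. FBLN1 is also in the matrix list. The summed level over the 15 entries of the 14 listed fibroblast markers was 85.9 CPM in the control, 66.3 in KO1 and 118 in KO2, so the clones differed in direction. The camera adjusted p of the fibroblast markers was 9.76e-05, and adjusted p = 0.664 with an estimated correlation.

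Of 38 tested epithelial genes, 10 fell and none rose (20 and 0 adjusted over the list alone; camera adjusted p = 4.86e-12). The largest falls were those of the tight junction genes TJP3 (5.16 ± 0.66) and CLDN4 (3.54 ± 0.63). Next were the epithelial transcription factor ELF3, which fell by 2.73 ± 0.54, and the tight junction gene CLDN7, which fell by 2.59 ± 0.67. OCLN, another tight junction gene, fell by 1.90 ± 0.56, with log2 ratios of -0.97 in KO1 and -5.29 in KO2. Of 23 tested genes of the classical pancreatic cancer subtype, 10 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 2.16e-11). The surface glycoproteins CEACAM6 and CEACAM5 fell by 5.36 ± 0.62 and 3.29 ± 0.63, the glycosyltransferase ST6GALNAC1 by 4.13 ± 0.74 and VSIG2 by 2.79 ± 0.63. Both calls were lost at an adjusted p = 0.664 with an estimated correlation. Of 30 tested genes of the basal-like subtype, 4 rose and 5 fell (6 and 7 adjusted over the list alone). KRT14 rose by 6.24 ± 0.73, and VGLL1, LY6D and SCEL fell by 7.33 ± 0.68, 6.78 ± 0.76 and 3.15 ± 0.46 (camera adjusted p = 0.501).

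**Figure D1:**
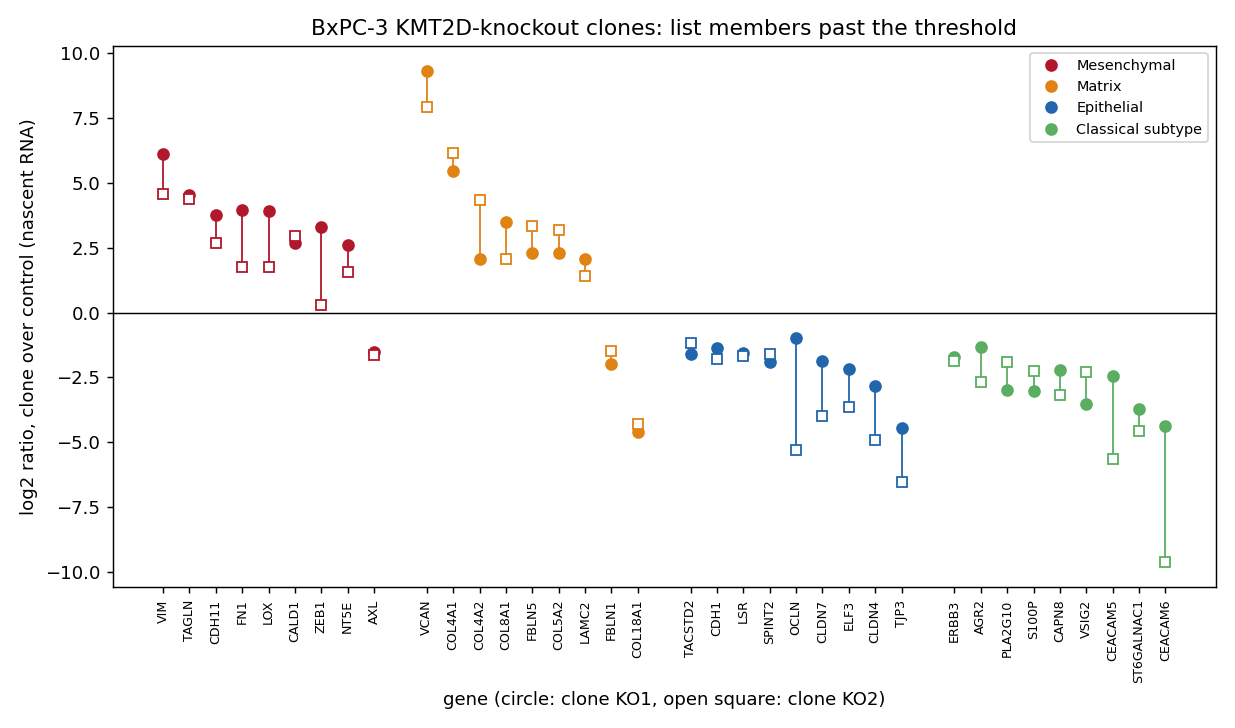
Log2 ratio of nascent RNA in each KMT2D-knockout clone over the BxPC-3 control line (y axis) for members of the mesenchymal, matrix, epithelial and classical subtype lists, shown where they passed the test (x axis), with circles for KO1 and open squares for KO2. VIM has log2 ratios of 6.11 and 4.56, and CEACAM6 of -4.38 and -9.63.

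Some inflammatory cytokine genes were also higher in the knockout clones. Of 26 tested NF-kB and cytokine genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 7.58e-05, and adjusted p = 0.664 with an estimated correlation). IL6 rose by 6.96 ± 0.90 (4 counts in the control, 525 and 957 in the clones), the neutrophil attractants CXCL1 and CXCL8 rose by 4.25 ± 0.68 and 2.89 ± 0.59, and TNFAIP3, a feedback inhibitor of NF-kB, rose by 2.59 ± 0.54. The growth factor CSF3 had 1 control count, with a log2 ratio of the clones of 5.96 and a counting interval from 3.47 to 11.3. Some genes of the unfolded protein and integrated stress response went the other way, with 9 of 25 lower and 1 higher (11 and 2 adjusted over the list alone; camera adjusted p = 2.96e-09, and adjusted p = 0.664 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell by 3.65 ± 0.44, SESN2 by 3.16 ± 0.44, the pseudokinase gene TRIB3 by 2.87 ± 0.44 and DDIT3, which encodes the stress factor CHOP, by 2.09 ± 0.45. Of 18 hypoxia genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0818), among them the oxygen sensor gene EGLN3 at 3.35 ± 0.54, CA12 at 2.75 ± 0.64 and NDRG1 at 2.62 ± 0.61. Of 22 immediate early genes, 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.877 with an estimated correlation). KLF6 was higher by 2.02 ± 0.50, while FOS, FOSB and ATF3 were lower at -1.93 ± 0.49, -1.89 ± 0.50 and -1.86 ± 0.49.

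The TGF-β target list did not move one way in the knockout clones (camera adjusted p = 0.973). Of its 27 tested members, 5 rose and 3 fell (5 and 4 adjusted over the list alone). SPHK1 rose by 4.17 ± 0.99, WNT11 by 3.23 ± 0.89, the matrix glycoprotein gene THBS1 by 2.81 ± 0.58 and CTGF by 2.80 ± 0.81, while LTBP3, which encodes a protein that anchors latent TGF-β, fell by 2.26 ± 0.57. Of 16 activin pathway genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.834). Beside INHBA and FST, the follistatin-like gene FSTL1 rose by 2.47 ± 0.51, and GDF15, which encodes a stress-induced cytokine of the TGF-β family, fell by 6.40 ± 0.60 (1306 counts in the control, 24 and 21 in the clones). Of 31 genes of p38, JNK and AP-1 signalling, 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.834). The kinase MAP2K6 was at 2.10 ± 0.67 and the phosphatases DUSP4 and DUSP10 at 1.85 ± 0.57 and 1.79 ± 0.51. None of 23 genes of the H3K4 methyltransferase list, which also holds other chromatin enzyme genes, passed, over all genes or adjusted over the list alone (camera adjusted p = 0.834).

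The largest single-gene differences involved genes near the detection limit on either side. With 0 counts in the control line, the glycine receptor subunit GLRA4 was at least 50.5-fold higher, the growth factor FGF5 at least 31.6-fold (275 counts in KO1 but 9 in KO2), the apelin gene APLN at least 22.1-fold and the interleukin IL20 at least 15.5-fold. S100A8, GIMAP4, KCCAT198, RGS4 and RFLNA were at least 13.2-, 12.8-, 12.7-, 12.4- and 9.76-fold higher, with RFLNA at 2 counts in KO1 and 82 in KO2. The chemokine CCL21 had 1 count in the control and 264 and 1244 in the clones, a log2 ratio with a counting interval from 6.52 to 14.3. With 0 counts in both clones, PDK4, an inhibitor of pyruvate dehydrogenase, was at least 43.0-fold lower, GGT6 at least 33.2-fold, the prostate stem cell antigen gene PSCA at least 18.6-fold and P2RX3 at least 14.7-fold. IGSF5, CAMK2A, CYP2W1, UBXN10, TMPRSS13, C2orf54 and GTSF1 were at least 14.2-, 13.7-, 13.7-, 12.2-, 10.8-, 10.8- and 10.3-fold lower. DMGDH, a choline catabolism enzyme, had 194 counts in the control and 1 in each clone, a log2 ratio of -8.15 with a counting interval from -11.2 to -6.28. All of these passed the edgeR test.

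The second comparison asked how PANC-1 transcription changed after 1, 24 and 72 h of TGF-β. Most direct TGF-β targets were higher at each time, more mesenchymal and matrix genes rose at 72 h than at 1 h, and most cell cycle genes fell at 24 h. Of the camera calls for these lists, that of the TGF-β targets at 1 h alone held with an estimated correlation. SMAD7 rose by 2.61 ± 0.30 at 1 h, 1.89 ± 0.29 at 24 h and 1.85 ± 0.30 at 72 h (additive edgeR fit, 2 libraries per time against 2 with vehicle). CDH1 rose by 1.39 ± 0.21 at 1 h and then fell by 1.31 ± 0.22 at 24 h and 3.14 ± 0.26 at 72 h. COL1A1, the main fibrillar collagen, rose by 3.18 ± 0.34, 4.91 ± 0.36 and 6.10 ± 0.38. VIM, already at 41376 nascent counts with vehicle, was at 0.55 ± 0.18 (adjusted p = 0.0664), 0.72 ± 0.18 and 0.61 ± 0.18, and passed at 24 and 72 h.

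At adjusted p under 0.05, 1415 genes rose and 485 fell at 1 h, 2074 rose and 2109 fell at 24 h, and 2323 rose and 2338 fell at 72 h, of 20318 tested. The 3 times share their vehicle libraries, and the counts depended on single libraries. At 1 h they were 655 and 152 without vehicle nascent RNA, 877 and 147 without the 1 h nascent library, and 938 and 211 without the 1 h chased library. They were 986 and 254 without vehicle chased RNA, 1796 and 870 without the 72 h nascent library and 1802 and 788 without the 72 h chased library. At 24 h they were 1341 and 1496 without vehicle nascent RNA, 981 and 675 without vehicle chased RNA, 1123 and 834 without the 24 h nascent library and 969 and 576 without the 24 h chased library. At 72 h they were 1317 and 804 without vehicle chased RNA, and 1816 and 1006 without the 72 h chased library. CDH1 and SMAD7 passed in this fit at all 3 times. With the 4 nascent libraries alone and the treated times as 1 group, edgeR called 0 of 20679 genes, with 1211 at an unadjusted p under 0.05.

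Of 26 tested TGF-β targets, 24 rose at 1 h, 21 at 24 h and 23 at 72 h and none fell (25, 24 and 25 adjusted over the list alone). PMEPA1, which encodes a feedback inhibitor of TGF-β signalling, rose by 3.85 ± 0.20 at 1 h, the SMAD corepressor gene SKIL by 3.65 ± 0.19 and the proprotein convertase gene FURIN by 3.68 ± 0.34. THBS1, CTGF and TGFBI rose by 4.41 ± 0.33, 4.02 ± 0.25 and 3.64 ± 0.24 at 72 h. The camera call at 1 h held at an adjusted p = 0.0367 with an estimated correlation, and those at 24 and 72 h did not (adjusted p = 0.109 and adjusted p = 0.0878 with an estimated correlation). In nascent RNA alone, the median log2 ratio of these targets was 2.08, 1.95 and 2.42, above all of 10000 random lists at each time. BMP-type targets rose at 1 h, with 6 of 8 higher and none lower (6 and 0 adjusted over the list alone), including HEY1 at 2.97 ± 0.32, ID2 at 2.69 ± 0.48 and ID1 at 2.18 ± 0.33. At 24 h 1 of the 8 rose and 1 fell, and at 72 h HEY1 rose while ATOH8 and SMAD6 fell (1 and 1, then 1 and 2, adjusted over the list alone). The BMP list had an adjusted p = 0.509 at 1 h with an estimated correlation.

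Of 37 mesenchymal genes, 12 rose at 1 h, 19 at 24 h and 23 at 72 h, and 0, 2 and 1 fell (16, 21 and 25 rose and 0, 3 and 2 fell adjusted over the list alone). SNAI1, a repressor of CDH1, rose by 3.45 ± 0.23 at 1 h, and LOX and CALD1 rose by 5.74 ± 0.39 and 4.52 ± 0.25 at 72 h. FN1 had 1 nascent count with vehicle and 926 after 72 h, a log2 ratio of 9.71 with a counting interval from 7.91 to 15.7. Of 32 matrix genes, 11, 16 and 18 rose and 0, 7 and 4 fell (12, 17 and 20 rose and 1, 8 and 6 fell adjusted over the list alone). COL4A1 and COL5A1 rose by 4.66 ± 0.28 and 4.52 ± 0.22 at 72 h, and the laminin gene LAMA5 fell by 2.51 ± 0.34 at 24 h. Of 32 epithelial genes, 4, 3 and 3 rose and 1, 10 and 14 fell (5, 4 and 3 rose and 2, 12 and 17 fell adjusted over the list alone). The keratins KRT19 and KRT18 fell by 3.30 ± 0.31 and 2.14 ± 0.23 at 72 h and the splicing factor gene ESRP2 by 2.05 ± 0.28, while CLDN1 fell by 1.87 ± 0.20 at 1 h and rose by 1.59 ± 0.19 at 24 h. With an estimated correlation, the 72 h calls had an adjusted p = 0.132 for mesenchymal, an adjusted p = 0.254 for matrix and an adjusted p = 0.132 for epithelial genes. Of 9 fibroblast markers, 2, 3 and 5 rose and 0, 1 and 0 fell (2, 3 and 5 rose and 0, 1 and 1 fell adjusted over the list alone). They were led by COL1A1, COL6A3 at 3.79 ± 0.24 and the receptor gene PDGFRB at 3.07 ± 0.46 at 72 h, with an adjusted p = 0.132 with an estimated correlation. The summed level of the fibroblast markers rose from 42.6 to 211 CPM in nascent RNA between vehicle and 72 h.

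**Figure D2:**
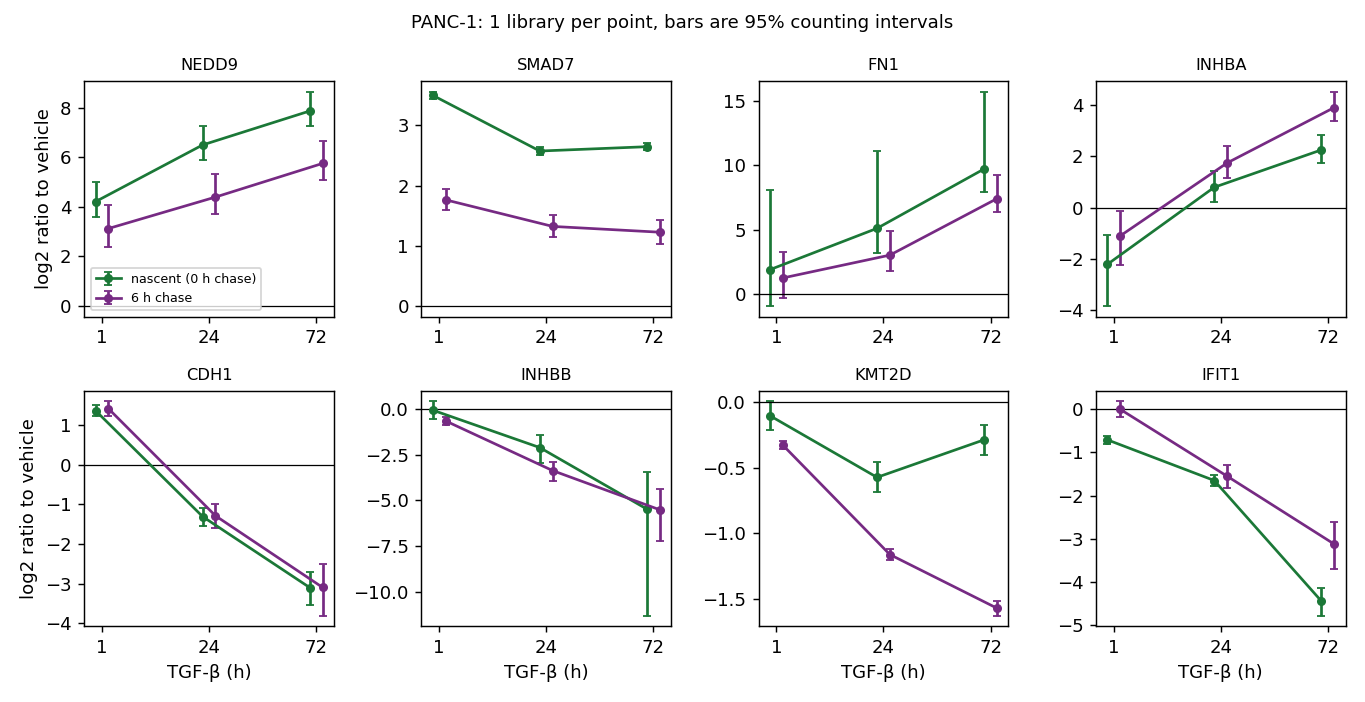
Log2 ratio of TGF-β over vehicle (y axis) against hours of TGF-β (x axis) in PANC-1 for 8 genes, in nascent RNA (green) and after 6 h of chase (purple), with 1 library per point and 95% counting intervals as bars. INHBB reaches -5.47 and CDH1 -3.10 in nascent RNA at 72 h, and KMT2D reaches -0.29 in nascent and -1.57 in chased RNA.

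Most cell cycle genes fell at 24 and 72 h. Of 42, 5 fell at 1 h, 38 at 24 h and 33 at 72 h and none rose (5, 39 and 37 adjusted over the list alone), with an adjusted p = 0.145 at 24 h and an adjusted p = 0.211 at 72 h with an estimated correlation. CDT1, a licensing factor of DNA replication, fell by 4.20 ± 0.48 at 24 h and 1.81 ± 0.40 at 72 h, and E2F1, a transcription factor of S-phase genes, fell by 3.11 ± 0.30 and 1.90 ± 0.29. CDKN1A, which encodes the CDK inhibitor p21, rose by 3.26 ± 0.22 at 1 h, 1.79 ± 0.21 at 24 h and 1.75 ± 0.21 at 72 h. Of the 14 growth arrest genes, 1, 5 and 4 rose and 1, 2 and 1 fell (1, 5 and 4 rose and 3, 3 and 1 fell adjusted over the list alone), with CDKN2C down by 1.87 ± 0.23 at 24 h. Of 35 interferon-stimulated genes, 3 fell at 1 h, 16 at 24 h and 24 at 72 h and none rose (1, 23 and 29 adjusted over the list alone). IFIT1, IFIT2 and IFIT3, which encode antiviral proteins that bind foreign RNA, fell by 3.93 ± 0.32, 3.38 ± 0.23 and 3.31 ± 0.29 at 72 h, and OASL by 3.07 ± 0.30, with an adjusted p = 0.105 with an estimated correlation for the list. Of 28 genes of cholesterol and fatty acid synthesis, 3, 0 and 0 rose and 3, 14 and 15 fell (4, 1 and 0 rose and 5, 19 and 18 fell adjusted over the list alone). FASN, the fatty acid synthase gene, fell by 2.98 ± 0.28 at 72 h, with an adjusted p = 0.211 with an estimated correlation for the list.

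More stress-response and immediate early genes rose than fell at 24 and 72 h, and camera called neither list with an estimated correlation. Of 25 genes of the unfolded protein and integrated stress response, 1 rose and 5 fell at 1 h, 17 rose at 24 h and 13 at 72 h (2 and 6, 17 and 1, and 17 and 1 adjusted over the list alone). The chaperone gene HSPA5 rose by 2.26 ± 0.17 and the cystine transporter gene SLC7A11 by 1.81 ± 0.20 at 24 h, and STC2 by 2.19 ± 0.19 at 72 h, with an adjusted p = 0.338 at 24 h with an estimated correlation for the list. Of 22 immediate early genes, 7, 13 and 13 rose and 0, 1 and 2 fell (9, 14 and 13 rose and 1, 2 and 2 fell adjusted over the list alone; adjusted p = 0.25 at 24 h with an estimated correlation). JUNB rose by 2.28 ± 0.34 at 1 h, and ATF3 rose by 3.44 ± 0.21 at 24 h and 3.41 ± 0.21 at 72 h. Of 30 genes of p38, JNK and AP-1 signalling, 6, 9 and 9 rose and 3, 7 and 7 fell (7, 10 and 11 rose and 5, 8 and 8 fell adjusted over the list alone). GADD45A rose by 1.91 ± 0.22 at 72 h, and the kinases MAPK12 and MAP2K6 fell by 1.72 ± 0.30 and 1.55 ± 0.27. Of 19 hypoxia genes, 6, 10 and 10 rose and 1 fell at each time (8, 10 and 12 rose and 2, 2 and 1 fell adjusted over the list alone; adjusted p = 0.211 at 72 h with an estimated correlation), led by LOX and ANGPTL4 at 3.36 ± 0.36 at 72 h.

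Activin ligand genes moved in opposite directions. INHBA fell by 1.73 ± 0.49 at 1 h (6 nascent counts against 40 with vehicle) and rose by 1.22 ± 0.38 at 24 h and 3.04 ± 0.38 at 72 h, while INHBB, the other activin subunit gene, fell at 24 h (-2.86 ± 0.35) and 72 h (-5.59 ± 0.48). FST rose at 1 h (adjusted p = 0.0181) and by 1.81 ± 0.62 at 72 h, and was at 0.66 ± 0.67 at 24 h (adjusted p = 0.527), on 3 to 10 nascent counts. Of 16 activin pathway genes, 3, 7 and 6 rose and 1, 1 and 2 fell (6, 7 and 6 rose and 1, 1 and 4 fell adjusted over the list alone). FSTL3 rose by 2.22 ± 0.31 at 1 h and the receptor gene ACVR1C by 1.92 ± 0.48 at 72 h (camera adjusted p = 0.349 at 72 h). SLC2A3 was at -0.81 ± 0.77 (adjusted p = 0.628) at 1 h and 1.74 ± 0.61 (adjusted p = 0.0539) at 24 h, and rose by 2.76 ± 0.60 at 72 h. KMT2D was at -0.23 ± 0.24 at 1 h (adjusted p = 0.665) and fell by 0.90 ± 0.24 at 24 h (adjusted p = 0.0156) and 0.95 ± 0.24 at 72 h (adjusted p = 0.0107). Of 23 genes of the H3K4 methyltransferase list, which also holds demethylase and other chromatin enzyme genes, 0, 9 and 10 fell and none rose (0, 11 and 12 adjusted over the list alone). They include PAGR1 at -2.21 ± 0.56, SETD1B at -1.13 ± 0.22 and KMT2B at -1.04 ± 0.26 at 72 h, with an adjusted p = 0.475 with an estimated correlation for the list.

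**Figure D3:**
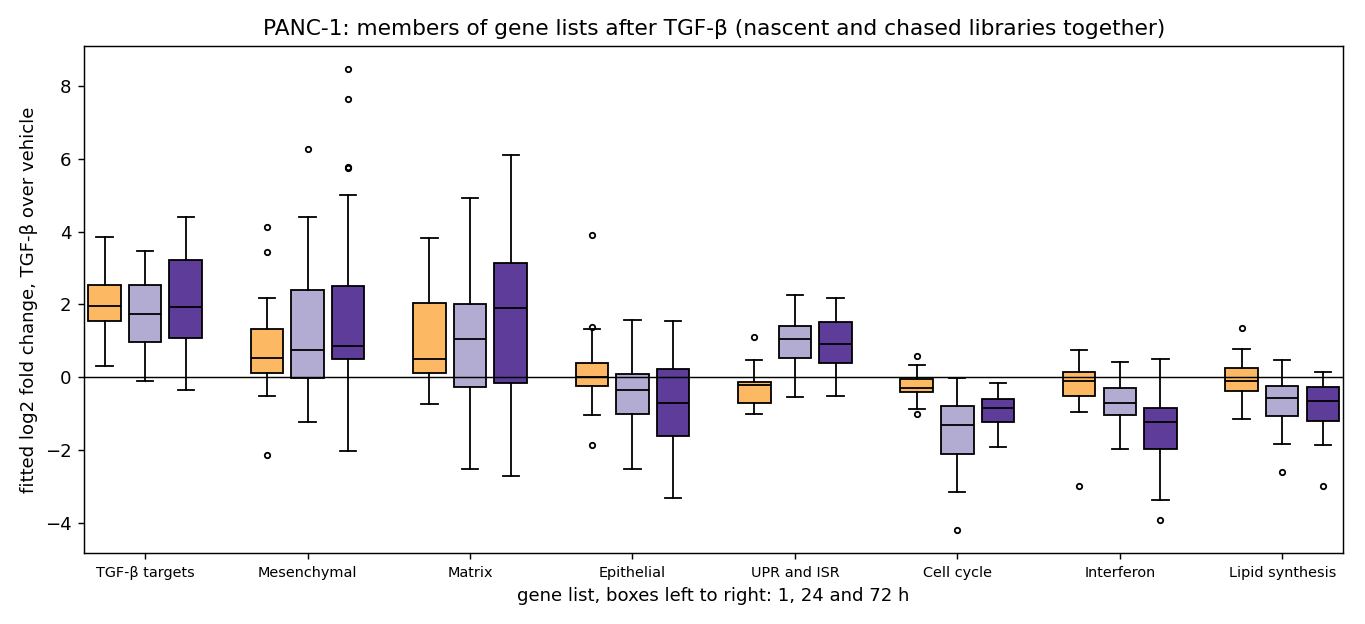
Fitted log2 fold change of TGF-β over vehicle (y axis) for the tested members of 8 gene lists (x axis) at 1, 24 and 72 h, as boxes of the middle members with median lines, whiskers to the farthest members within the usual range and open circles beyond. The median of the TGF-β targets is 1.96, 1.73 and 1.93, that of the cell cycle genes -0.29, -1.32 and -0.85, and that of the interferon-stimulated genes -0.10, -0.71 and -1.21.

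In nascent RNA alone, 1359 of 16813 genes were at least 2-fold higher and 579 lower at 1 h, 1475 and 1024 at 24 h, and 1764 and 874 at 72 h. At 1 h the largest nascent ratios included NKILA, a noncoding inhibitor of NF-kB, at 5.18 (4.58 to 5.94), and WNT4 at 4.90 (3.99 to 6.23). With 1 to 3 vehicle counts, NXPH4 was at 5.95 (4.10 to 11.9), PKP1 at 5.71 (4.19 to 9.15), RNF152 at 5.54 (4.02 to 8.98), DACT1 at 5.32 (3.44 to 11.3), KANK4 at 5.25 (3.72 to 8.70) and ADAMTSL2 at 5.15 (3.81 to 7.71). Lowest at 1 h were PDK4 at -3.45 (-5.50 to -2.16), the EGF receptor ligand EREG at -3.03 (-3.41 to -2.68), FGF5 at -2.74 (-3.01 to -2.48), C9orf84 at -2.60 (-3.37 to -1.95), and TRPA1 at -2.52 (-3.03 to -2.06). Also low were the WNT inhibitor DKK1 at -2.48 (-2.60 to -2.37), ASB4 at -2.47 (-2.84 to -2.13) and THSD1 at -2.29 (-2.53 to -2.06). At 24 h the adhesion scaffold gene NEDD9 was at 6.50 (5.90 to 7.28), the growth factor gene FGF1 at 5.43 (4.74 to 6.38) and VGLL3 at 5.42 (4.81 to 6.21). CDH19, DACT1, ITGA11 and KANK4, with 1 to 3 vehicle counts, were at 6.78 (5.48 to 9.33), 6.74 (4.92 to 12.7), 5.97 (4.47 to 9.41) and 5.18 (3.65 to 8.62). PTGS2, the inducible cyclooxygenase gene, had 0 nascent counts with vehicle and was at least 9.13-fold higher at 24 h and at least 41.2-fold higher at 72 h. Lowest at 24 h were ASB4 at -4.82 (-5.65 to -4.17), the helicase gene RECQL4 at -4.30 (-6.37 to -3.07), SAMD10 at -3.54 (-5.14 to -2.47), and MUC16 at -3.44 (-4.00 to -2.96). Next were AGR2 at -3.39 (-3.63 to -3.17), FAM111B at -3.33 (-3.58 to -3.10), PKMYT1 at -3.33 (-3.91 to -2.84) and CDT1 at -3.26 (-4.72 to -2.25).

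At 72 h the large nascent ratios beside FN1 included NEDD9 at 7.87 (7.27 to 8.65) and FGF1 at 7.86 (7.18 to 8.80). On 1 to 3 vehicle counts, ITGA11 was at 8.39 (6.91 to 11.8), CDH19 at 8.03 (6.74 to 10.6), DACT1 at 7.84 (6.03 to 13.8) and the protease gene ADAMTS9 at 7.76 (6.47 to 10.3). Lowest were INHBB at -5.47 (-11.3 to -3.45) on 1 count after 72 h, the phosphatase subunit gene PPP2R2B at -4.65 (-5.19 to -4.19), IFIT1 at -4.44 (-4.77 to -4.13), and ASB4 at -4.25 (-5.00 to -3.64). Next were NECAB1 at -3.83 (-4.80 to -3.07), the mucin gene MUC16 at -3.76 (-4.47 to -3.17), PDK4 at -3.72 (-6.21 to -2.29) and the chemokine gene CCL5 at -3.59 (-4.45 to -2.90). In chased RNA, 847 of 15637 genes were at least 2-fold higher and 627 lower at 1 h, 1391 and 1848 at 24 h, and 1762 and 2345 at 72 h. FN1 was at 7.41 (6.35 to 9.21) and CCL5 at -4.84 (-8.11 to -3.16) in chased RNA at 72 h. Nascent and chased log2 ratios correlated over genes with r = 0.748, 0.763 and 0.735, and 93.7%, 95.2% and 92.9% of the genes past 2-fold in nascent RNA had the same sign in chased RNA. Genes are not independent replicates, so no p-value is given.

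Scaling by library totals alone shifted the median gene by -0.13 at 1 and 24 h in nascent RNA and by -0.21 at each time in chased RNA, and the ratios above are relative to the TMM reference. It moved the share of higher genes among those past 2-fold from 70.1% to 57.9% at 1 h and from 59.0% to 47.5% at 24 h in nascent RNA. In chased RNA it moved that share from 57.5% to 32.9%, from 42.9% to 25.1% and from 42.9% to 28.9% at 1, 24 and 72 h.

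The third comparison set RNA after 6 h of chase against nascent RNA over the 4 PANC-1 conditions. The counts cover introns and exons alike, so its differences can also move with splicing. Most ribosomal protein and immediate early genes had lower shares in chased RNA, in libraries scaled to their own totals, and the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.968). Of 52 ribosomal protein and elongation factor genes, 50 fell and 2 rose (50 and 2 adjusted over the list alone), with RPS27 at -4.07 ± 0.20 and RPL7 at -2.92 ± 0.16. Many of these genes have processed pseudogenes that share their sequence, so the values are uncertain. Of 22 immediate early genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone), with the phosphatase gene DUSP1 at -2.96 ± 0.26, EGR1 at -2.79 ± 0.19 and KLF6 at -2.53 ± 0.22, whose mRNAs are known to be short-lived. Of the fixed genes, KMT2D rose by 3.33 ± 0.19, FST by 1.79 ± 0.42 and INHBA by 1.06 ± 0.28, and SMAD7 fell by 3.46 ± 0.22 and VIM by 0.43 ± 0.12. CDH1 at -0.31 ± 0.16 (adjusted p = 0.108) and SLC2A3 at -0.56 ± 0.45 (adjusted p = 0.285) did not pass.

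Over all genes, 6741 rose and 6970 fell after the chase, of 20318 tested (edgeR, condition as a block). Highest among named genes were DCAF4L1 at 6.47 ± 0.33, SBSN at 5.39 ± 0.62, the amine oxidase gene AOC3 at 5.21 ± 0.40, the potassium channel subunit gene KCNE4 at 4.99 ± 0.91, C2orf66 at 4.93 ± 0.26 and the claudin gene CLDN2 at 4.88 ± 0.85. Lowest were ZC2HC1B at -5.46 ± 0.75 and OLFML3 at -5.00 ± 0.84. The others named by rule share sequence with other genes and are uncertain: HNRNPKP2 at 6.12 ± 1.08, RPS3AP29 at 5.27 ± 0.79, HNRNPKP4 at 4.84 ± 0.54 and FAM60BP at 4.81 ± 0.88. Lower and uncertain in the same way were BOLA2P3 at -7.64 ± 0.89, BOD1P1 at -7.22 ± 0.96, the readthrough gene RPL17-C18orf32 at -5.37 ± 0.40, SOD2P1 at -5.05 ± 0.58, RN7SL76P at -4.82 ± 0.74, RNVU1-6 at -4.77 ± 0.74, RPL21P5 at -4.75 ± 0.48 and MRPL37P1 at -4.67 ± 0.67. The nuclear noncoding RNAs MALAT1 and NEAT1 together took 5.94% to 10.7% of the counts in chased libraries and 0.632% to 1.07% in nascent PANC-1 libraries.

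The fourth comparison asked how TGF-β changed the chase to nascent ratio, a measure meant to follow RNA stability. Of 14863 genes, 156 were at least 2-fold higher and 585 lower at 1 h, 338 and 850 at 24 h, and 594 and 1591 at 72 h. The 1 h values depended on low counts. With a mean of at least 100 counts, 222 of 10856 genes passed 2-fold at 1 h, and the share of higher genes went from 21.1% to 6.31%. With all libraries thinned to the counts of the shallowest, the 72 h values were 482.6 higher (427 to 512) and 1342.7 lower (1296 to 1410) on average over 10 thinnings. At 24 h the highest were ASB4 at 3.17, SLFN12L at 2.55, the deubiquitinase gene YOD1 at 2.13 and ADTRP at 1.99. Low at 24 h were KANK4 at -3.18, on 2 nascent and 3 chased counts with vehicle, and NOXA1 at -3.07. NXPH4 and WNT4 were lowest by rule too, but had 2 and 3 chased counts with vehicle and 0 at 24 h, so no value is given. At 72 h the highest were SLFN12L at 2.58, the pseudogene FAM21FP at 2.48 (uncertain), the BMP target ID2 at 2.47 and the chemokine gene CXCL8 at 2.33, and the lowest were SLC15A3 at -3.99, MGAM at -3.31, the desmosome gene PKP1 at -3.30 and RPH3A at -3.28. Library totals alone moved the share of higher genes at 72 h from 27.2% to 16.4%, with a median shift of -0.12.

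KMT2D itself had a lower chase to nascent ratio under TGF-β, by -0.22 at 1 h, -0.59 at 24 h and -1.28 at 72 h. The nascent ratio of KMT2D was -0.11 (-0.21 to 0.004), -0.57 (-0.69 to -0.46) and -0.29 (-0.40 to -0.17), and its chased ratio -0.33 (-0.36 to -0.30), -1.16 (-1.20 to -1.12) and -1.57 (-1.62 to -1.51). SMAD7 was at -1.74, -1.25 and -1.42. INHBA was at 1.11, 0.95 and 1.65, VIM at 0.38, -0.35 and -0.06, and SLC2A3 at 0.40 and 0.32 at 24 and 72 h, with 1 nascent count at 1 h. CDH1 was at 0.05, 0.02 and 0.00, so its nascent and chased ratios moved alike. FST was under the count minimum for these ratios. Replication-dependent histone genes had a median change of 0.62 at 1 h, -0.86 at 24 h and -1.03 at 72 h over 12 genes, at percentiles 100, 0.14 and 0.32 of matched random lists. At 72 h, 7 of the 12 were at least 2-fold lower and none was higher. The zinc finger genes with short-lived mRNA had medians of 0.02, 0.39 and 0.53, at percentiles 99.96 and 99.98 at 24 and 72 h. Matrix genes had -0.08, -0.57 and -0.59 and TGF-β targets -0.05, -0.38 and -0.42. Genes at least 2-fold higher in nascent RNA had medians of -0.47, -0.49 and -0.42, a choice that by itself lowers this ratio, so the values of both lists are not set apart from those of induced genes at large. Because the counts cover introns and exons alike, these ratios can also move with splicing.

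**Figure D4:**
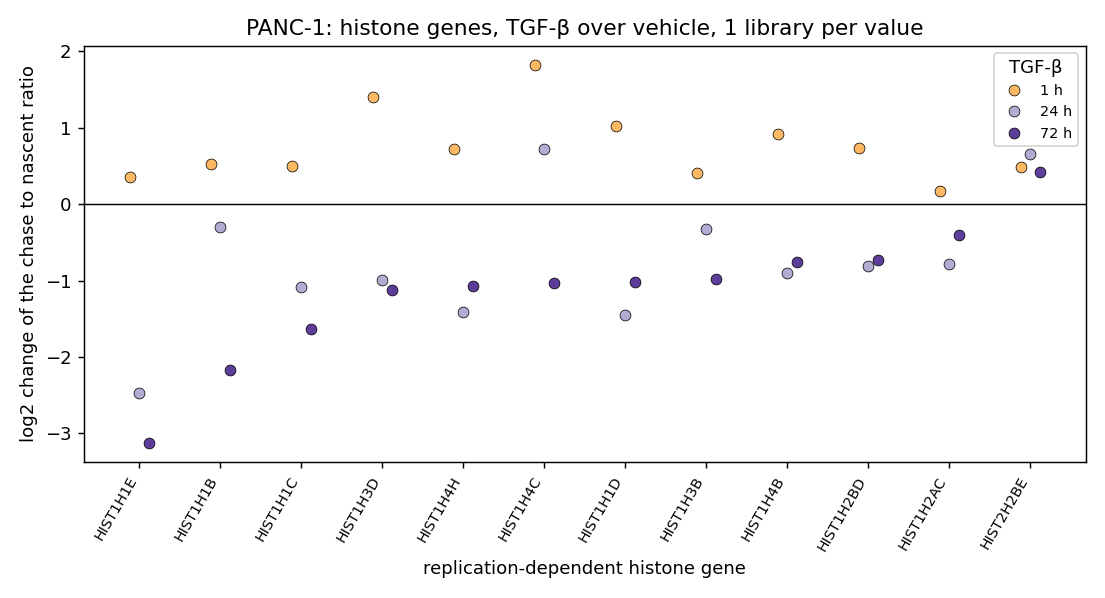
Change of the log2 chase to nascent ratio under TGF-β (y axis) for 12 replication-dependent histone genes (x axis) in PANC-1 at 1, 24 and 72 h, with 1 library per assay and condition behind each point. The median is 0.62 at 1 h, -0.86 at 24 h and -1.03 at 72 h.

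The last comparison set the knockout changes in BxPC-3 beside the TGF-β changes in PANC-1, which share no library. Genes such as VCAN, COL4A1, FN1, LOX, INHBA, THBS1 and CTGF rose in the knockout clones and after 72 h of TGF-β, with log2 fold changes of 8.85, 5.88, 3.27, 3.23, 4.96, 2.81 and 2.80 in the clones. Of 18201 genes in both fits, 135 rose in both at 72 h where independent lists would give 39.4, 121 fell in both against 65.7, 26 rose in the clones and fell with TGF-β against 42.5, and 114 fell in the clones and rose with TGF-β against 60.9. SMAD7 is in that last group. At 24 h these counts were 106 against 36.0, 107 against 59.4, 26 against 38.4 and 94 against 55.7. At 1 h they were 55 against 24.1, 34 against 13.4, 14 against 8.66 and 95 against 37.3. At 1 h every group thus exceeded its value for independent lists, and the excess had no single direction. Genes that fell in the clones and rose with TGF-β were the most numerous at 1 h, but also under independent lists. At 24 and 72 h, genes that rose in the clones and fell with TGF-β were fewer than independent lists would give. The other groups exceeded that value at both times. Over 15915 genes, the knockout change and the nascent TGF-β ratio were close to unrelated, with r = -0.039, 0.052 and 0.095 and rho = -0.017, -0.0044 and 0.013 at 1, 24 and 72 h. Genes at least 2-fold lower in PANC-1 nascent RNA at 72 h (788 tested) were shifted down in the clones, with 66 lower and 12 higher (77 and 13 adjusted over the list alone; camera adjusted p = 0.00881, and adjusted p = 0.674 with an estimated correlation). The 1540 genes higher at 72 h were not, with 119 higher and 97 lower (142 and 119 adjusted over the list alone; camera adjusted p = 0.614). Neither were the 1281 higher and 958 lower at 24 h (96 higher and 90 lower, and 15 higher and 55 lower, or 111 and 111, and 17 and 61, adjusted over the list alone; camera adjusted p = 0.853 and 0.614).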

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

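The tests of differences between time points in this part were chosen after the separate time points had been examined, and the other tests before their results were seen. Of 44 genes named by rule and tested, 35 differed between 72 h and 1 h of TGF-β in the additive edgeR fit (adjusted p under 0.05), 18 of them higher and 17 lower at 72 h. Many of them were named for a large ratio at 1 of these times, so a difference between the times is partly built into the choice. Values are differences of log2 fold changes. PTGS2, ADAMTS9, FN1, ITGA11 and CDH19, whose levels were near 0 with vehicle, were higher at 72 h by 7.12, 6.99, 6.86, 5.33 and 4.96. The growth factor gene FGF1, the adhesion gene NEDD9, DACT1, KANK4 and VGLL3 were higher by 3.59, 3.14, 2.61, 2.06 and 0.98, and SLC2A3 and RNF152 by 3.57 and 1.76. C9orf84, FGF5, EREG, TRPA1 and DKK1, low at 1 h, had differences of 2.18, 1.31, 1.29, 1.17 and 0.74. INHBA changed direction, from lower at 1 h to higher at 72 h, with a difference of 4.76. CDH1 changed direction the other way, with a difference of -4.54. The cell cycle and replication genes CDT1, PKMYT1 and RECQL4 were lower at 72 h than at 1 h by differences of -1.22, -1.78 and -1.99, and SAMD10, ASB4, AGR2 and NECAB1 by -1.51, -1.87, -1.92 and -2.61. ADAMTSL2, NXPH4 and WNT4, high at 1 h, had differences of -3.03, -3.52 and -4.52. PPP2R2B, IFIT1, CCL5, MUC16 and INHBB had differences of -3.50, -3.56, -3.94, -4.30 and -5.19. Over all genes, 2390 were higher and 2665 lower at 72 h than at 1 h, and 142 were called in opposite directions.

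KMT2D differed between 72 h and 1 h by -0.73, and its chase to nascent ratio changed by -1.28 at 72 h. Thinning all libraries to the shallowest left changes of -1.41 to -1.18 over 10 thinnings. Thinning keeps the expected ratio of a gene, and KMT2D had 950 to 1687 nascent and 3051 to 17805 chased counts in PANC-1. The outcome was thus close to fixed in advance, and it shows only that counting noise at that depth did not remove the change. KMT2D ranked at percentile 0 among 200 genes of like length and nascent level, whose median change was -0.051. A trend with length or nascent level is therefore excluded as the whole cause. Genes of like chased level were not compared, so a trend with that level stays open. TGF-β may shorten the life of KMT2D RNA or change its processing, and counts over the whole gene cannot tell these apart. Splicing, 1 library per point and whether TGF-β stayed on during the chase were not tested and stay open.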

How the results depend on the processing

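All tests here were chosen before their results were seen, and the cause of a moved value was not tested. No paired analysis was possible by replicate number because every group in PANC-1 and the BxPC-3 control holds 1 library. Chased against nascent RNA was paired by condition as a block, with 13711 genes called. Without the block 9863 were called, and INHBA and VIM did not pass. Of the counts and correlations, 159 stayed the same, 77 moved and 1 reversed. Of the named genes, 1298 values were the same, 138 weaker, 15 stronger and 6 reversed.

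In the knockout comparison, leaving out a clone gave 1190 to 1915 higher and 1480 to 1858 lower genes, with the spread then taken from all 11 libraries, where both clones gave 614 and 847. DESeq2 gave 394 lower and limma-voom 217 higher genes. The share of higher genes among those called was 40.3% in the main fit, 50.1% with DESeq2 and 30.4% with limma-voom. The excess of lower genes thus depended on the method. At least 2-fold in the remaining clone were 2453 to 2636 higher and 2794 to 3717 lower genes, which follows from asking 1 clone and not both, and with a mean of at least 100 counts 589 and 709 in both.

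A mean of at least 100 counts leaves fewer genes, which gave these higher and lower counts for 1, 24 and 72 h. In nascent RNA they were 243 lower at 1 h, 910 and 558 at 24 h and 1098 and 428 at 72 h. In chased RNA they were 537 and 293, 812 and 1185, and 1091 and 1470. For the change of the chase to nascent ratio they were 14 and 208, 120 and 394, and 263 and 891. Chased against nascent RNA gave 4300 and 4490. With library totals alone, chased RNA had 1244 lower genes at 1 h and 900 higher at 24 h. The correlation of nascent and chased changes was 0.827, 0.794 and 0.757 with a mean of at least 100 counts, and 0.626, 0.708 and 0.625 by Spearman.

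In the additive fit, leaving out 1 library gave 655 to 1802 higher and 147 to 870 lower genes at 1 h, 969 to 2771 and 576 to 2716 at 24 h, and 1317 to 2412 and 804 to 2739 at 72 h. The nascent libraries alone gave 0 higher and 0 lower at 1 h, 0 and 0 at 24 h, and 0 and 0 at 72 h, which has fewer libraries and averages the times. For the same reason INHBA at 1 h reversed to 1.14, SLC2A3 at 1 h to 1.67 and CDH1 at 24 and 72 h to 0.045 each. With 1 library left out, KMT2D at 1 h ranged from -0.52 to 0.14, reversed without the vehicle chased library. SLC2A3 at 1 h ranged from -4.09 to 0.72, reversed without the 1 h nascent library.

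With an estimated correlation, camera called 0 lists for the knockout, 1 for TGF-β at 1 h, 0 at 24 h, 0 at 72 h and 0 for chased against nascent RNA. That setting has 1 degree of freedom in the knockout fit and 3 in the PANC-1 fit, which leaves little room for calls. The fry test called 0 for the knockout, 1 at 1 h, 15 at 24 h, 17 at 72 h and 10 for chased against nascent RNA. The correlation of knockout and TGF-β changes was -0.0166 at 1 h, -0.00442 at 24 h (reversed) and 0.0134 at 72 h by Spearman, 0.00937 at 24 h and 0.0561 at 72 h with clone KO2 alone, and 0.0332 at 24 h with a mean of at least 100 counts.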

Other observations

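The tests for a scaling shift and for fewer cells in S phase behind the histone pattern were chosen after the result was seen. SMAD4 had 0 counts in all 3 BxPC-3 libraries and 2417 to 5676 in PANC-1, so INHBA, VIM and some matrix genes were higher in clones of a line without this mediator. Genes shared by the knockout and 72 h of TGF-β, picked after their values were seen, include endothelin EDN1 at 6.75 and 3.52, the gap junction gene GJA1 at 6.22 and 4.03, STC1 at 6.49 and 2.78, NNMT at 4.88 and 5.16, ADAMTS6 at 3.68 and 5.09 and PTHLH at 2.21 and 3.87 (log2, clones and TGF-β). In the knockout clones, 2 of 20 p53 targets fell and none rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.00335, and adjusted p = 0.664 with an estimated correlation). The apoptosis gene BBC3 was at -2.97. Of 13 growth arrest genes 1 fell (3 adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.664 with an estimated correlation). None of 42 cell cycle genes passed in the clones, or adjusted over the list alone. Of 29 cholesterol genes 1 fell (2 adjusted over the list alone; camera adjusted p = 0.0238, and adjusted p = 0.664 with an estimated correlation). None of 8 BMP-type targets passed (2 fell adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.877 with an estimated correlation). None of 17 histone genes passed, or adjusted over the list alone, while camera placed the list lower (adjusted p = 0.00135, and adjusted p = 0.877 with an estimated correlation). Among 23 glycolysis genes 1 rose and 2 fell, among 34 interferon-stimulated genes 1 fell, and among 13 heat shock genes 1 fell, with the same counts adjusted over the list alone. Of 20 zinc finger genes 1 fell (2 adjusted over the list alone), and none of 52 ribosomal protein, 31 oxidative phosphorylation and 4 leukocyte genes passed, or adjusted over the list alone. Among 7 endothelial markers TEK rose by 4.67, ERG by 3.64 and VWF fell by 2.73, and of 3 neural markers SNAP25 rose by 4.46 (2 and 1, and 1 and 0, adjusted over the list alone).

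In PANC-1 with TGF-β, more glycolysis genes fell than rose at 24 and 72 h. Of 25, 6, 1 and 2 rose and 2, 11 and 11 fell at 1, 24 and 72 h (6, 3 and 2 rose and 2, 13 and 11 fell adjusted over the list alone; camera adjusted p = 0.0018 at 24 h, and adjusted p = 0.503 with an estimated correlation). ALDOA was at -1.68 and GAPDH at -1.55 at 24 h. Of 21 NF-kB and cytokine genes, 3, 4 and 8 rose and 5, 7 and 5 fell (3, 4 and 8 rose and 5, 9 and 6 fell adjusted over the list alone). IL11, a known TGF-β target cytokine, was at 3.74 at 1 h and TNFAIP2 was at -2.73 at 72 h. Of 15 classical subtype genes, 3 rose at each time and 1, 4 and 6 fell (3 at each time and 3, 4 and 6 adjusted over the list alone). Of 11 basal-like genes 2, 4 and 4 rose and 2, 1 and 2 fell, with the same counts adjusted over the list alone. Of 20 p53 targets, 2, 5 and 2 rose and 1, 1 and 2 fell (3, 6 and 2 rose and 3, 2 and 2 fell adjusted over the list alone). Of 16 histone genes, 0, 2 and 2 rose and 0, 2 and 0 fell (0, 2 and 0 rose and 0, 4 and 0 fell adjusted over the list alone). Of 13 heat shock genes, 1, 0 and 0 rose and 0, 2 and 2 fell (1, 0 and 0 rose and 1, 3 and 2 fell adjusted over the list alone), with HSPA1A at -1.09 at 72 h. Of 52 ribosomal protein genes, 0, 2 and 2 rose and 0, 2 and 4 fell (0, 1 and 0 rose and 0, 2 and 1 fell adjusted over the list alone). Of 31 oxidative phosphorylation genes, 1, 0 and 0 rose and 0, 3 and 5 fell (1, 0 and 0 rose and 0, 3 and 4 fell adjusted over the list alone), with CYC1 and NDUFB10 each at -1.40 at 24 h. Of 20 zinc finger genes, 0, 6 and 3 rose and 2, 0 and 0 fell (0, 7 and 3 rose and 2, 0 and 0 fell adjusted over the list alone; camera adjusted p = 0.0298 at 24 h, and adjusted p = 0.573 with an estimated correlation). Of 7 neural markers, 0, 3 and 2 rose and 0, 1 and 1 fell, with the same counts adjusted over the list alone, including SNAP25 at 1.19 at 24 h. Of 3 leukocyte markers 1 rose at each time and 0, 1 and 1 fell (1, 2 and 2 rose and 1 fell at each time adjusted over the list alone). Of 3 endothelial markers none passed (1, 0 and 1 rose adjusted over the list alone). No acinar or islet marker passed the filter in a fit, and their summed level was 0.110 to 1.43 CPM.

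Some mesenchymal and matrix genes such as VIM and COL4A1 were higher, and some epithelial genes lower, in the knockout clones. Over the 25 passing members that moved these ways, the median size was 2.82. The passing mesenchymal and matrix members that fell, AXL, COL18A1 and FBLN1, were left out of this set and of the tests on it. Neighbouring genes moved by a median of 0.167 in the same direction (0.0580 to 0.347), and 75 genes abundant in PANC-1 and absent from the control reached a median of 0.0131% of their PANC-1 level in the clones (0 to 0.0457%) where 2580% would be needed, so copy number and PANC-1 RNA are excluded as the whole cause. LSR and SPINT2 on chromosome 19, picked after their values were seen, fell by 1.62 and 1.73 and their neighbours by 0.85 and 0.79, so copy number stays open for part of these changes. After thinning to the depth of the control, as few as 16% of the members still passed (median 68%, up to 92%) at sizes of 2.81 to 2.89, so the number that passes depends on depth and this stays open. Loss of KMT2D may shift BxPC-3 cells toward a mesenchymal state, or the clones may have differed before editing. With a single control line this was not tested.

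Replication-dependent histone genes had a chase to nascent ratio lower by a median of -1.03 after 72 h of TGF-β. Thinning left -1.19 to -0.817. Because thinning keeps the expected ratio of a gene, this shows only that counting noise at that depth did not remove the change. The median lay at percentile 0.32 of matched random lists, whose own median was -0.30. A factor shared by all genes cannot move that rank, so a scaling shift is excluded as the whole cause, and part of the change is shared with other genes. Fewer cells in S phase, where histone mRNA is stable, could lower it, and cell cycle genes had a nascent median of -1.02 at percentile 0. The nascent median of histone genes was 0.38 at percentile 91.9, so it was not lower, and the chased median was -0.62 at percentile 11.99, so the rank of the ratio rests in part on the nascent side. At 1 h cell cycle genes were at percentile 0 as well (-0.34) while the histone ratio was higher (0.62), so this stays open. No cell cycle measurement was used here.

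In fits without condition as a block, which the reported comparison has (13711 genes called), 35 ways to split the 8 PANC-1 libraries into equal groups were tried. Of these, 1 called as many genes as the split by assay (9863), which is that split itself, and the highest other called 228. Every other split mixes nascent and chased libraries, so the difference between the assays counts as spread within its groups. The split with 228 set vehicle and 1 h of TGF-β against the later times, which is itself a difference of condition. The splits therefore cannot show how many genes chance would call, and no conclusion on chance is drawn from them. In windows of 50 neighbouring genes, 21 of 268 had a median beyond 0.5 in KO1, 5 in KO2, and 3 in both with the same sign. Of those 3, 2 are on chromosome 12, namely the window that holds KMT2D (-0.76 and -0.53) and that from 56116586 to 62622213 (-0.57 and -0.51). The other is on chromosome 19 from 41193049 to 44500523 (-0.92 and -0.65). From 37613749 to 58558960 on chromosome 19, all 7 windows had medians of -1.22 to -0.65 in KO1. From 14522 to 62622213 on chromosome 12, all windows had medians of -0.83 to -0.19 in KO1 and -0.59 to -0.41 in KO2. The chase to nascent difference was lower for the shortest and the longest genes, with medians of -0.22, 0.18, 0.10 and -0.19 over 4 groups of rising length (rho = -0.000275). Gene length was weakly related to nascent changes under TGF-β (rho = 0.109, 0.185 and 0.128).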
